A study of Bacillus subtilis with 9 samples.

How the data were processed

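RNA-seq libraries were made from Bacillus subtilis JH642 and from a yplP mutant of it. Per the labels' protocols, shaken cultures grew at 37 °C in a minimal medium with glucose to an OD of 0.5 and were then moved to 15 °C or kept at 37 °C for 0.5 h or 2 h. Which library had which time, and how the exponential and stationary labels relate to these times, is not given in the sources used here, nor is the kind of mutation in yplP. Cells were broken with glass beads and total RNA was taken with phenol/chloroform and a column kit, per the labels' protocols. The labels place 9 libraries in 8 groups of genotype, growth phase and temperature. The yplP mutant in stationary phase in the cold has 2 libraries and each of the other 7 groups has 1. Nothing says that the 2 libraries came from separate cultures, so the spread between them may be technical. The p-values measure only the spread between the libraries at hand, which for main effects and interactions also holds differences between conditions.

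Bowtie2 is named, without a version, in the submitters' processing notes. The annotation source, the counting program, the read filters and the use of strand are not given in the sources used here. The deposited values named counts are a coverage signal, the sum of covered bases of each gene, as their lowest values and totals show, so no count model was used and the number of reads is unknown. The deposited RPKM are coverage scaled by gene length and library size, on a scale the authors do not describe in the sources used here. The deposited normalized RPKM are these RPKM multiplied by 1 factor per library, which varied by at most 0.0016% between the genes of a library. Median normalized RPKM per library lay between 930.8 and 969.0. A series table was not used here, since 2 of its columns belong to no sample given. The files list 4421 genes (4243 mRNA, 86 tRNA, 30 rRNA and 62 other RNA genes), and 4239 locus tags matched the reference gene table, which was used for names and neighbours only. Gene positions are those of the files. Of these genes, 54 overlap a gene on the opposite strand, and their values could hold signal of both.

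Normalized RPKM were tested as log2(value + 1) with limma 3.58.1 in R 4.3.3 (trend and robust options, two-sided, Benjamini-Hochberg adjustment, threshold 0.05). A fold change is therefore on the log2(value + 1) scale, which understates the change of low genes. Genes at 10 or more normalized RPKM in at least 2 libraries were kept, 4349 in all. This minimum was set after the values were seen and before any test. The effects of cold, genotype and growth phase were each fitted over all 9 libraries with the 4 combinations of the other factors as blocks (4 residual degrees of freedom). The spread in these fits is that of the effect between the 4 blocks plus the replicate pair. An effect that differs between conditions therefore has a larger SE. Whether the cold effect differed by genotype or by phase was tested as an interaction in a model with every interaction of 2 factors (2 residual degrees of freedom). Contrasts of single groups came from a model of 8 group means with 1 residual degree of freedom, in which each lone library is assumed to vary like the replicate pair. In all, 7 comparisons were planned and 2 contrasts, both within exponential phase, were added after the data were seen. Folds within a single condition carry no test.

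Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, with camera at an estimated correlation, and with fry, which asks whether a list's genes move on balance one way. In each comparison 35 lists with at least 3 tested genes were adjusted together. The lists, the groups, the 7 planned comparisons and the rule for named genes were fixed before the data were examined. The list tests for cold by phase and for cold in the stationary mutant were added later. That rule names yplP, the genes of pyruvate transport, the cold shock proteins and the desaturase system, then the 10 highest and 10 lowest folds of each main effect among genes with an adjusted p under 0.05, the same sign in 4 blocks and at least 20 RPKM in the higher group (5 each way for the other comparisons; rRNA and tRNA genes left out), and up to 4 members of each list that passed, or 2 where none did. This rule was narrowed for length after the values were seen. Members of lists that did not pass are named for the cold effect and for sulfur genes in cold by phase, and elsewhere only members of some lists that passed. The rule's top genes within single conditions are not named: 95 of the 120 stand against a library listed at 0, and 13 of 120 with a minimum of 1000 added later. yplQ, tRNA genes and the phosphate starvation, cytochrome bd, nitrate reductase and lactate genes were examined after their values were seen, the first as the call of a planned comparison.

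Alternatives were median-ratio scaling, quantile normalization, removal of rRNA and tRNA genes before scaling, no minimum and a minimum of 20 RPKM, pseudocounts of 0.1 and 5, a 2-fold threshold, models without blocks, the replicate pair averaged, and each library left out. The count models planned for read counts, as the main test and as alternatives, were not run because the files hold none, and the written fallback, limma, was used. The tests were tested on simulated data with the real genes, 50 changed at each of 4 sizes. At a log2 fold of 2, 66% were recovered for the cold effect, 68% for the yplP effect, 68% for growth phase, 40% for cold by genotype and 36% for cold by phase. For the yplP contrast in stationary cold libraries 0% were recovered even at a log2 fold of 4, and for the cold contrast in the stationary mutant 4% at 2 and 44% at 4. Simulated lists without change gave 0 calls of 35 in each comparison, with noise drawn independently for each gene. Depth per library was 361 to 2022 Mb of covered bases. In the replicate pair the SD of the log2 difference was 1.75 over all genes and 0.553 over genes above 5000, and 28.3% of all genes differed by over 2-fold. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the files and drew the plots.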

Results

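Transcript levels were measured by RNA-seq in Bacillus subtilis JH642 and in a yplP mutant, in exponential and stationary phase, at 37 °C and after transfer to 15 °C. The series title names YplP as a regulator of pyruvate transport at low temperature. YplP belongs to a family of activators that work with the sigma factor SigL. Coverage summed over genes was 2022, 543, 730 and 729 Mb in the wild-type libraries (exponential 37 °C, exponential cold, stationary 37 °C, stationary cold) and 444, 361, 488, 820 and 390 Mb in the mutant libraries in the same order. The last pair are stationary cold replicates 1 and 2. The share of that coverage on mRNA genes was lower in the cold than at 37 °C within each genotype and phase, and higher in the mutant than in the wild type in each matched condition. In the same order it was 55.4%, 39.5%, 46.9% and 32.3% in the wild type and 65.6%, 48.0%, 74.1%, 49.5% and 64.8% in the mutant. Most of the rest lay on 2 stable RNAs, scr (8.2% to 38.3%) and ssrA (14.4% to 25.2%). Between 15 and 298 genes were listed at 0 in a library, the fewest in the deepest, and the read depth behind each value is unknown. Coverage of 100 nt per kb of gene stood for 2.07 to 9.23 normalized RPKM in the 37 °C libraries and 6.76 to 14.89 in the cold ones. The floor was thus higher in the cold, which limits calls of low genes as lower there. The labels give growth phase as the time point of a library. How phase relates to the 0.5 h and 2 h after transfer at an OD of 0.5 is not given, so phase and time after transfer are not separated. Unless a replicate is named, each group is a single library with no replicate check.

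yplP itself was higher in the cold in the wild type and low in the mutant. Normalized RPKM of yplP (BSU21780, positions 2294286 to 2295281) were 411.4 at 37 °C and 12585.1 in the cold in exponential wild-type cells, and 691.3 and 11632.1 in stationary ones. The mutant libraries lay between 104.1 and 184.0, and the highest of them stood at 44.7% of the lowest wild-type library, so the target gene matched the genotype labels in 9 of 9 libraries. Averaged over conditions the mutant was lower by a log2 fold of −4.25 ± 0.72 (SE, limma adjusted p = 0.0489), a call that ended without any of the 9 libraries in turn (log2 fold −4.93 to −3.47). The next gene on the same strand, yplQ (BSU21790, 2295302 to 2295943), moved with yplP in the wild type, from 1359.2 to 60431.4 and from 2460.6 to 41717.4 in the cold. In the mutant it was high at both temperatures, at 22911.1, 24051.0, 33696.3, 35055.4 and 35216.5.

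**Figure D1:**
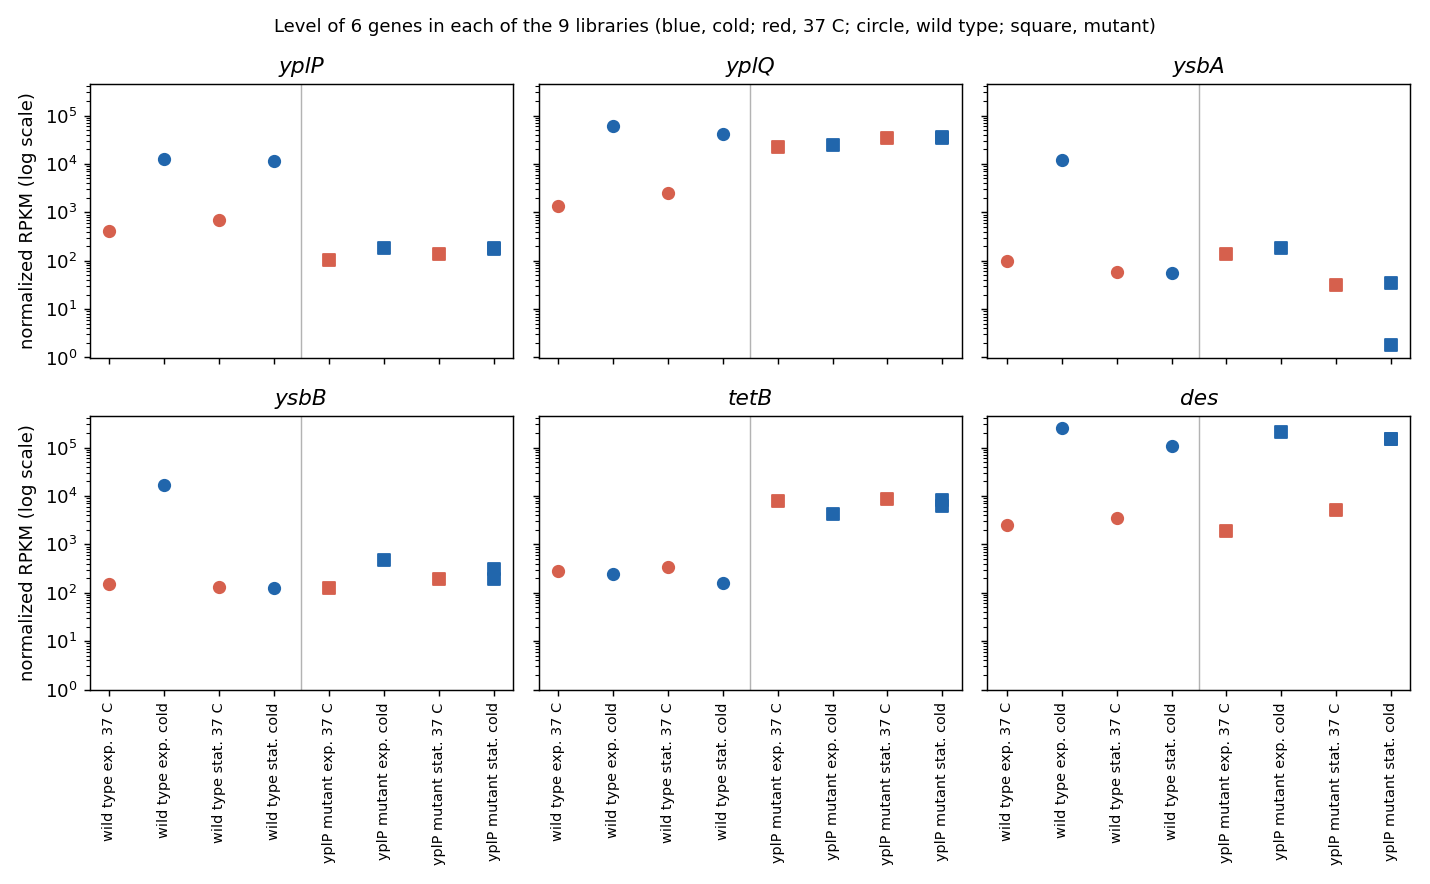
Normalized RPKM of 6 genes in each of the 9 libraries, on a log scale, with wild-type libraries as circles, mutant libraries as squares, 37 °C in red and cold in blue. ysbA and ysbB stand above 10000 in the wild-type exponential cold library alone, tetB is higher in each mutant library than in each wild-type library, and yplQ is high in each mutant library at both temperatures.

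The first question was which transcripts respond to cold. The membrane desaturase system held the 2 smallest adjusted p-values. In it desK and desR, the sensor and regulator, rose by log2 folds of 6.60 ± 0.30 and 6.36 ± 0.29 (limma adjusted p = 1.42e-05 for both), and des, the fatty acid desaturase, by 5.72 ± 0.35 (0.000106). Of the cold shock proteins, RNA chaperones, cspC rose by 2.97 ± 0.27 (0.000386) and cspB by 1.09 ± 0.24 (0.0116), whereas cspD did not pass (0.62 ± 0.23, 0.0759). Among genes with the same sign in the 4 blocks, the other largest rises were those of tuaA (BSU35610; teichuronic acid synthesis, 6.79 ± 0.88, 0.00143), cydD (cytochrome bd assembly, 5.38 ± 0.40, 0.000172), the phosphate uptake genes pstA (5.31 ± 0.70), pstC (5.21 ± 0.71) and pstS (4.88 ± 0.62), yjbC (4.33 ± 0.28) and the spore protein gene sspF (4.26 ± 0.45). Without that condition on sign, 2 more genes would stand among these. They are a second tuaA entry (BSU35609, 5.59 ± 1.35, limma adjusted p = 0.0177), whose fold in the stationary wild type was −0.62, and ykzW, listed at 0 in 1 library. yplP rose on average by 2.39 ± 0.74 (0.0437), a mean over both genotypes. The 10 lowest folds were those of ykzV, cotZ, spoVFA, ymaG, ywbE, yppG, cotI, ycbL, yozS and yvzH, among them spore coat and sporulation genes. Each was listed at 0 in at least 1 cold library, so no fold is given, and their means at 37 °C were 94.6 to 3066.5.

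By gene list, that of the SigL regulon had 14 genes that rose and 2 that fell of 26 (sigL 2.29, levF 1.96, bcd 1.65, rocR −2.02). The list also holds regulator genes such as sigL itself and rocR, so it is not made up of SigL targets alone. The bkd operon of branched-chain amino acid breakdown, part of that regulon, had 5 of 7 that rose (bcd, buk 1.10, bkdAB 1.07, bkdAA 0.94). In the list of ribosomal proteins 22 rose and 1 fell of 56 (rpmJ 1.99, rpsE 1.96, rpmD 1.94, rpsH 1.94). Its median was set against random lists of like expression, drawn from all kept genes, tRNA and rRNA genes included. It stood at percentiles 1.8 and 10.4 in exponential and stationary wild type and 23.2 and 98.1 in the mutant. The tRNA genes had a higher median level than mRNA genes, and 79 of 86 rose in the cold (median 1.91). These percentiles therefore do not compare the list with mRNA genes alone. In that of RNA helicases and ribonucleases 4 of 11 rose (cshA 1.26, cshB 1.21, rnr 1.12, rnc 0.78). Its median stood at percentiles of 47.3 to 83.5 among such random lists in the 4 conditions. That of the cold shock proteins stood at 37.4 to 79.1. Neither list was set apart from this mixed pool, and a comparison with mRNA genes alone was not made. Rises were also seen in 10 of 44 general stress genes of SigB (yjbC, yoxB 2.84, yocB 2.63, yflT 2.63) and 16 of 32 genes of the prophage PBSX (xkdD 2.27, xkdE 1.72, xkdU 1.62, xkdW 1.58). The wall and teichoic acid list had 9 of 19 that rose and 2 that fell (tagB 1.99, tagO 1.99, cwlO −1.92, lytE −1.87), and the nitrogen list 5 of 16 that rose and 1 that fell (glnR 2.31, nasF 1.92, amtB 1.86, nasE 1.85). Osmoprotectant uptake fell in 9 of 18 genes (opuBA −3.10, opuBC −2.94, proH −1.74, opuBB −1.51). The biofilm matrix fell in 3 of 19 (yuaB −2.19, epsD −2.07, tasA −1.82) and purine synthesis in 2 of 15 (guaB −2.15, guaA −1.24). The averaged direction did not hold in every condition. In the wild type the purine median was −1.36 in exponential and 1.38 in stationary phase (13 of 15 above 0), and it was below 0 in both phases of the mutant (−2.30 in exponential). The matrix median was −1.66 and 0.04 in the wild type and −2.93 and −0.26 in the mutant. That of general stress was −0.22 in the exponential mutant and 0.77 to 1.65 in the other 3 conditions. These lists and those of the desaturase system (3 of 3 rose) and the cold shock proteins (2 of 3 rose) were the 13 of 35 that camera called, 10 up and 3 down. With an estimated correlation none passed (smallest adjusted p = 0.747 with an estimated correlation, from limma's camera), and fry called 11 lists. The estimate rests on 4 residual degrees of freedom, and even the desaturase list did not pass with it, so this lack of calls says little. In 26 of 100 splits of the libraries, the real one included, as many lists were called. The ribosomal protein list turned to the other direction under quantile normalization (adjusted p = 0.654), where its call ended.

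Lists that did not pass as a whole still held genes that changed. The heat shock chaperones groES (−2.50), htpG (−2.46) and groEL (−2.25) fell while clpE rose (2.30), with 5 up and 7 down of 18. In the sulfur amino acid list 6 rose and 5 fell of 15 (yrhB 3.68, mccA 3.25, metA −2.31, yjcI −2.19). In the envelope stress list of SigX and SigW 9 rose and 7 fell of 28 (ydjH −2.09, ydjI −2.07, sigM 2.02, ydjG −1.91). Carbon catabolite genes rose in 7 and fell in 1 of 33, led by glycerol use (glpD 3.41, glpF 3.41, glpK 2.77) and gntR (1.83). Motility genes rose in 8 of 28 (mcpA 1.33, cheD 1.33, sigD 1.29, flhA 1.09). Translation factors had 6 up and 2 down of 17 (infA 1.93, bipA 1.48, infB 1.47, rbfA 1.39) and fatty acid synthesis 5 up and 3 down of 16 (ylpC 1.91, plsX 1.30, fabHB 1.30, plsC 1.27). Competence had 3 up and 2 down of 23 (comK −2.57, comC −2.42, srfAB 1.24, srfAC 0.97, the last turning sign under quantile normalization). Secretion and transition state genes had 3 up and 3 down of 18 (degQ 2.67, abrB 1.93, wprA −1.82, vpr −1.38) and sporulation 2 up and 1 down of 31 (sdpA −2.62, spoIIE 1.77, spoIIQ 1.28). In pyruvate metabolism lctP (1.57) and malS (0.91) rose and eutD (−1.52), ackA (−1.05) and 1 more fell of 25. In the lists of the citric acid cycle citZ (1.16) rose and fumC (−1.01) and sucC (−0.99) fell of 12, in gluconeogenesis gapB (3.62) rose of 4, and in glycolysis pgi (−1.09) fell of 11. In amino acid and nucleotide synthesis ilvD (−1.43) and ywaA (−0.71) fell of 11 branched-chain genes, hisG (−1.10) and hisZ (−1.02) fell of 8, trpC (1.29) rose of 6, and pyrG (−1.01) fell and pyrP (0.82) rose of 12. Iron uptake had 3 that fell of 23 (yfiZ −0.88, yfiY −0.81, yfhA −0.74) and ATP synthase 1 of 9 (atpB −1.15). None of 9 arginine synthesis genes passed (argF 1.36, carB (BSU11240) 1.32), nor did any of the 4 pyruvate transport genes.

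In all, limma called 1146 of 4349 genes in the cold (659 higher, 487 lower), with 217 expected at an unadjusted p under 0.05 and 1726 found. Of these, 1114 had the same sign in the 4 blocks, and 915 changed at least 2-fold. Stable RNA genes made up part of the rises: 79 of 86 tRNA, 14 of 30 rRNA and 32 of 62 other RNA genes were higher. The rRNA genes held only 0.05% to 0.114% of the coverage of a library. Their values may thus reflect removal or filtering rather than rRNA level, which was not tested. The share of higher calls in the cold effect, 57.5%, was 47.4% under quantile normalization (562 higher, 623 lower). Without the wild-type exponential 37 °C library the count was 528, without the wild-type exponential cold library 532 and without the mutant stationary 37 °C library 708. Of 121 named genes called for the cold effect, 47 lost the call without some library. These include the 10 with the lowest folds and 0 of the 10 with the highest. The cspB call ended without either of the first 2 libraries, and that of yplP without any wild-type library or mutant stationary cold replicate 2 (log2 fold 1.63 to 3.27).

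**Figure D2:**
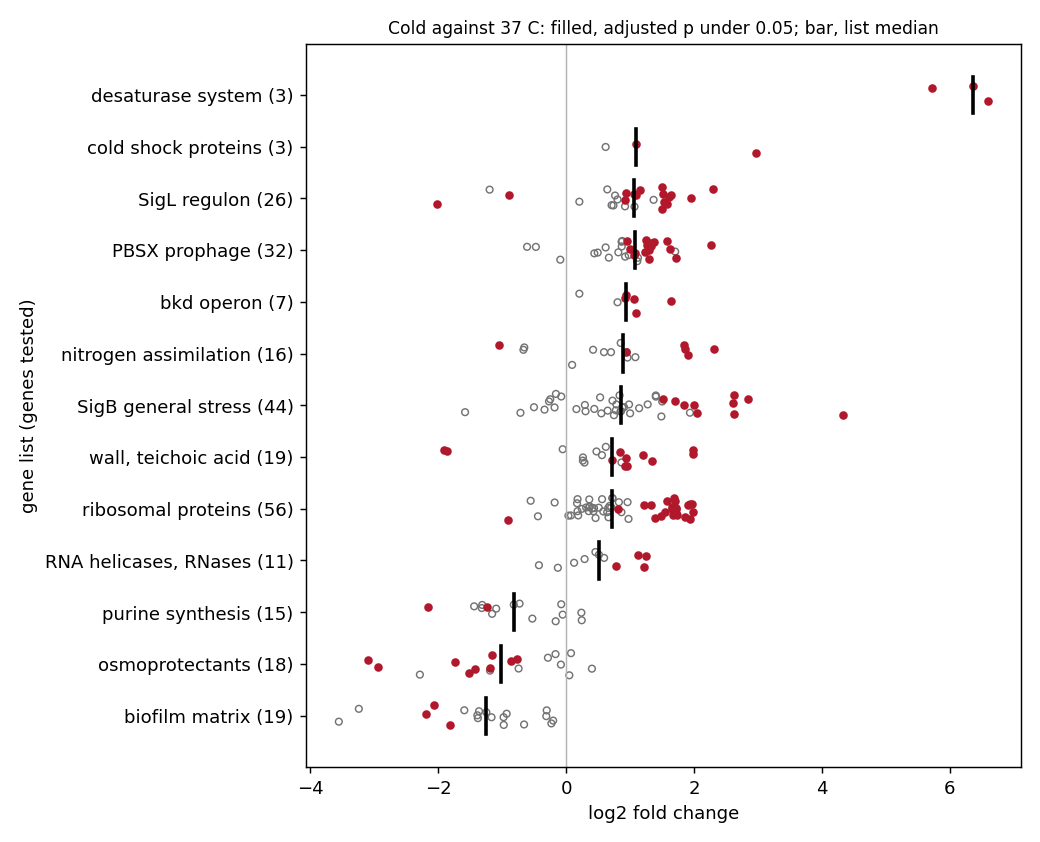
Log2 fold change in the cold against 37 °C, averaged over genotype and phase, for the members of the 13 gene lists that camera called, with the number of genes tested. Each point is a gene, filled where limma's adjusted p was under 0.05, and the bar is the list median. The 3 desaturase genes lie between 5.72 and 6.60, while the ribosomal list, whose direction turned under quantile normalization, centres on 0.71.

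The next question was what the yplP mutation changed over all conditions. Beside yplP, the largest difference was in tetB (BSU40770), a tetracycline resistance efflux gene, which was higher in the mutant by a log2 fold of 4.83 ± 0.25 (limma adjusted p = 0.000117). It stood at 155.6 to 342.7 normalized RPKM in the wild-type libraries and at 4249.4 to 8830.2 in the mutant. yxiI (1.49 ± 0.23), the chemotaxis gene cheY (1.17 ± 0.17) and the ribosomal genes rpsN (BSU01290; 1.17 ± 0.17), rplR (1.10 ± 0.17) and rplV (0.91 ± 0.16) were also higher. yczE (−1.28 ± 0.20), ytwF (−1.08 ± 0.16), yqhP (−1.02 ± 0.16), yvoF (−0.91 ± 0.13) and ydzA (−0.85 ± 0.14) were lower. The remaining 20 calls were tRNA genes, all lower, in libraries whose mRNA share of coverage also differed by genotype. The 86 tRNA genes lay below 0 in 86 cases, with a median of −1.09, which was −1.04 under median-ratio scaling and −1.02 under quantile normalization. Of other stable RNA, 28 of 30 rRNA and 53 of 62 other RNA genes also lay below 0. The limit on rRNA values given for the cold effect holds here too. The cold shock and desaturase genes did not differ detectably, with log2 folds of −0.32 to 0.30 and a smallest adjusted p of 0.503. The 6 genes around yplP and yplQ lay at −0.94 to 0.33 and none was called.

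Among gene lists, all 28 motility genes lay above 0 (median 0.71), of which cheY alone rose, and 21 rose when adjusted over the list alone. The ribosomal list had 3 that rose of 56, with 22 up and 3 down adjusted over the list alone; its median was −0.27 in stationary phase at 37 °C and 0.31 to 0.43 elsewhere. The biofilm matrix had 19 of 19 genes below 0 (median −0.80) with 0 called and 3 adjusted over the list alone. epsN stood at −1.98 ± 0.57, and sipW was listed at 0 in 1 mutant library, so no fold is given. Motility and matrix genes are often used by different cells of a culture. camera also called osmoprotectant uptake (down; median −0.31, gbsA −0.74, opuCD −0.74), general stress (up; median 0.32, bmrU 1.62, yfkT listed at 0 in 4 mutant libraries) and the citric acid cycle (up; median 0.16, odhB 0.42, mdh 0.40), with no member called. The general stress median was 1.14 in exponential phase at 37 °C and 0.56 in stationary cold, but −0.19 in exponential cold and −0.28 in stationary phase at 37 °C, so the averaged rise stands for 2 of 4 conditions. None of these 6 lists passed with an estimated correlation (smallest adjusted p = 0.947 with an estimated correlation) or with fry, and 73 of 100 splits of the libraries, the real one included, called as many.

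limma called 32 genes in all (6 higher, 26 lower; 654 at an unadjusted p under 0.05). Among the 12 named genes called, tetB alone kept its call without each library in turn. The count was 1 without any of 6 libraries (wild-type exponential 37 °C, stationary 37 °C or stationary cold, mutant exponential 37 °C, stationary 37 °C or stationary cold replicate 2) and, for the yplP effect, 56 without either exponential cold library. Under median-ratio scaling 24 were higher and 34 lower, under quantile normalization 1 and 3, and with rRNA and tRNA genes left out 14 and 6.

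The title's pyruvate transport was examined in ysbA and ysbB, neighbouring genes whose reference symbols are pftA and pftB (pyruvate transporter), and in lytS and lytT, the sensor and regulator pair encoded upstream. ysbA (BSU28910, 2955209 to 2955649) was at 11900.2 and ysbB (BSU28900, 2954492 to 2955187) at 16819.1 normalized RPKM in the wild-type exponential cold library. In the other 8 libraries ysbA lay between 1.8 and 178.9 and ysbB between 123.2 and 483.5. Among random lists of like expression, the median cold fold of the 4 transport genes in the exponential wild type (3.43) stood at percentile 100, and that of mutant against wild type in exponential cold (−2.95) at percentile 0.2, both resting on that 1 library and on ysbA and ysbB. The median cold fold was −0.23 in the stationary wild type (percentile 45, 0 of 4 above 0), −0.02 in the exponential mutant (54.2) and −0.51 in the stationary mutant (24.5), and mutant against wild type in stationary cold gave −0.50 (12.5). In exponential cold cells the mutant stood below the wild type by log2 folds of −6.05 ± 2.37 for ysbA and −5.12 ± 0.86 for ysbB. In a contrast added after the data were seen, neither passed over all genes (limma adjusted p = 0.717 for both), and adjusted over the list alone ysbB did (0.0244) and ysbA did not (0.143). In stationary cold libraries, where wild-type yplP was nearly as high, wild-type ysbA and ysbB were at 55.7 and 123.2, and the contrast of mutant with wild type gave −2.52 ± 2.05 and 0.98 ± 0.75 (adjusted p = 0.887 and 0.864). The effects averaged over conditions were, for ysbA and ysbB, cold 1.13 ± 1.39 and 2.10 ± 0.99, yplP −2.26 ± 1.15 and −0.82 ± 0.90, and phase −3.73 ± 1.21 and −1.84 ± 1.08. They had limma adjusted p of 0.152 to 0.747 over all genes and 0 calls of 4 adjusted over the list alone in each. The signs of the cold effect on ysbA (−0.59) and of the yplP effect on ysbB (0.48) turned without the wild-type exponential cold library. lytS and lytT changed by −0.30 ± 0.25 and −0.60 ± 0.23 in the cold (adjusted p = 0.413 and 0.0869) and by −0.48 ± 0.21 and −0.17 ± 0.23 in the mutant (0.332 and 0.798).

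Whether the mutation altered the cold response was tested as an interaction. yplQ was the single gene called, its cold effect being lower in the mutant by a log2 fold of −4.67 ± 0.38 (limma adjusted p = 0.0396; 282 genes at an unadjusted p under 0.05). yplP showed −3.87 ± 0.60 (0.249), ysbA −3.93 ± 2.13 (0.768) and ysbB −2.03 ± 1.32 (0.81), and the 6 cold shock and desaturase genes 0.07 to 0.78 (smallest adjusted p = 0.768). Synthesis of arginine (9 of 9 below 0, median −1.99; carB (BSU11240) −2.57, carA −2.25), pyrimidines (10 of 12, −1.67; pyrD −2.61, pyrK −2.44), purines (13 of 15, −1.57; purH −2.02, purM −2.002) and histidine (8 of 8, −1.04) stood lower in the mutant's cold response, with no member called over all genes and 8, 8, 13 and 5 lower adjusted over each list alone, where 1 pyrimidine and 1 purine gene were higher. camera called 13 lists, 12 down and 1 up, but none passed with an estimated correlation (smallest adjusted p = 0.587 with an estimated correlation) or with fry, and 9 of 60 splits called as many. The yplQ call was lost without 8 of the 9 libraries in turn, all but mutant stationary cold replicate 1, with 1 residual degree of freedom left, at log2 folds of −5.40 to −4.02. Across the 2272 genes with a mean of 1000 or more, wild-type and mutant cold folds had a Pearson correlation over genes of 0.846 in exponential and 0.774 in stationary phase, against 0.470 and 0.378 across all 4349 genes; genes are not independent replicates.

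Whether the cold response differed between the libraries labelled exponential and stationary gave more calls, as the plot of the cold effect by phase shows. This difference is not separated from one in time after transfer. The fold in stationary phase minus that in exponential phase was positive for yjcZ (5.86 ± 0.63), the nitrite reductase gene nasD (3.91 ± 0.43), carA (3.63 ± 0.31), the matrix coat gene yuaB (3.61 ± 0.38) and the toxin gene wapA (3.60 ± 0.42; limma adjusted p = 0.0168 for each). It was negative for yrrT (−5.45 ± 0.62) and the teichuronic acid genes tuaC (−5.23 ± 0.60), tuaG (−4.92 ± 0.85) and tuaE (−4.60 ± 0.82), and for des (−1.80 ± 0.27, 0.0319), whose rise was smaller in stationary cells. It was also negative for ykzW, which was listed at 0 in the mutant exponential 37 °C library, so no fold is given, and whose call ended at pseudocounts of 0.1 and 5. The interaction was positive and called in 7 of 9 arginine genes (carA, carB (BSU11240) 3.23, argB 3.12, argD 2.94), 7 of 15 purine genes (purL 2.97, purQ 2.90, purH 2.83, purF 2.64), 10 of 23 competence genes (comGD 3.29, comFB 3.12, comEA 3.05, comGA 3.03) and 5 of 28 motility genes (fliM 2.25, flhB 2.14, fliS 1.96, cheA 1.82). Adjusted over each list alone these were 9, 13, 18 and 17. Calls in other lists were rplC (1.76), rpsC (1.76), tsf (2.06), frr (2.06), atpE (1.84), tpiA (1.76), dps (2.79) and, negative, pyrR (−2.05) and msmX (−2.61). In the sulfur list mccA (−4.34), yrhB (−3.87) and cysK (−2.39) were negative and metE (3.02) positive. ysbA (−4.36 ± 2.13, 0.317) and ysbB (−4.07 ± 1.32, 0.16) did not pass.

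limma called 104 genes for this interaction (72 positive, 32 negative; 885 at an unadjusted p under 0.05) and camera 19 of 35 lists, 16 positive and 3 negative, of which none passed with an estimated correlation (smallest adjusted p = 0.477 with an estimated correlation) or with fry. Without any single library other than the mutant stationary cold replicates the count was 0; in cold by phase without replicate 1 it was 425 and without replicate 2 it was 105. The general stress list turned direction without the mutant stationary 37 °C library or either mutant exponential library.

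**Figure D3:**
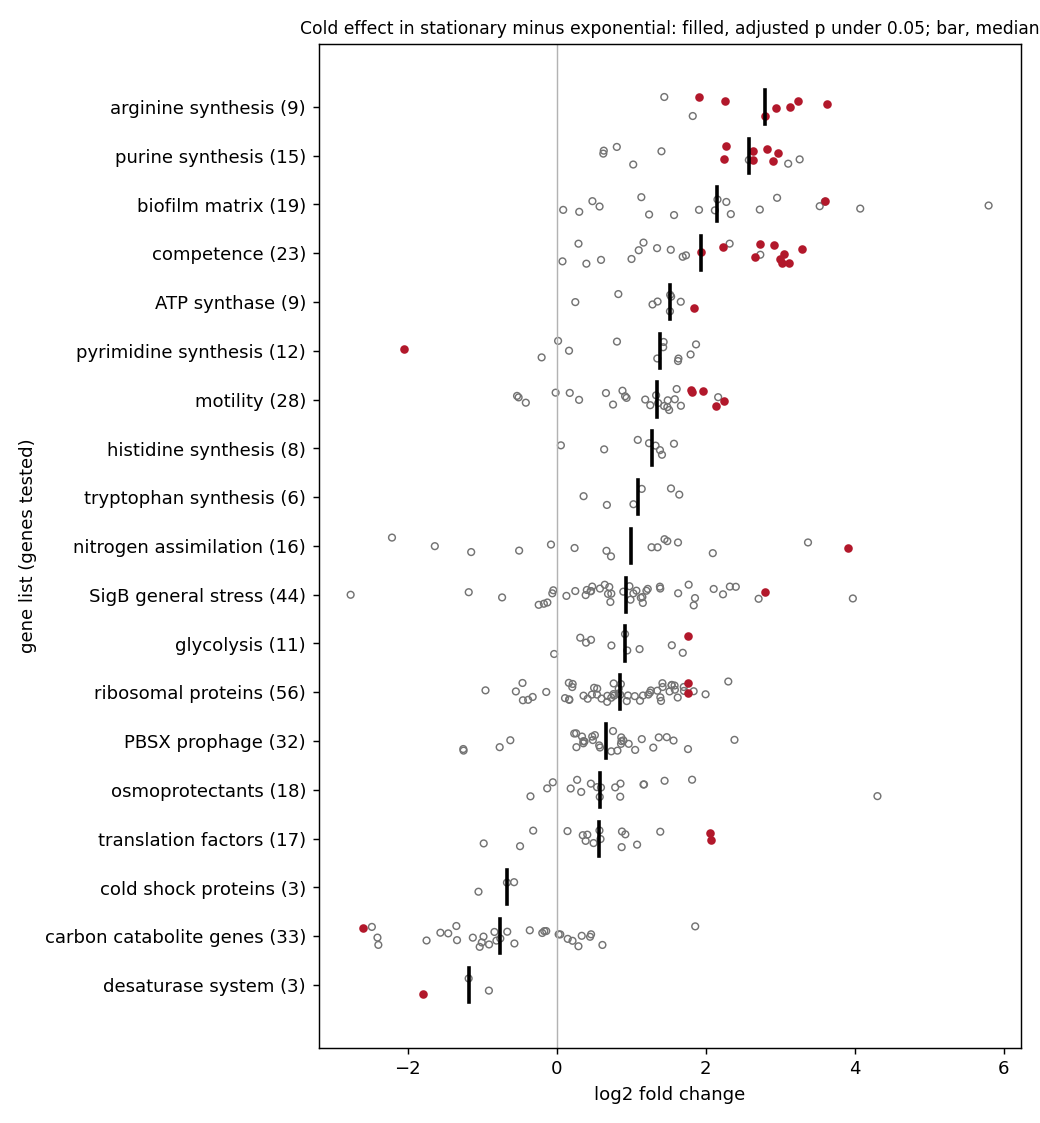
Difference of the cold effect between phases, stationary minus exponential, in log2 units, for the members of the 19 gene lists that camera called, with the number of genes tested. Each point is a gene, filled where limma's adjusted p was under 0.05, and the bar is the list median; arginine synthesis (median 2.79) and the desaturase system (−1.18) stand at the ends.

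Growth phase itself, or time after transfer, averaged over genotype and temperature, gave 0 calls with limma (smallest adjusted p = 0.0697; 541 genes at an unadjusted p under 0.05, 217 expected). Among the named genes yplP stood at 0.22 ± 0.30, the 6 cold shock and desaturase genes at −0.36 to −0.01 and ysbA at −3.73 ± 1.21 (adjusted p = 0.322, and 0.0574 adjusted over the list alone). camera called 11 lists, 5 up and 6 down, among them heat shock proteins (down; 16 of 18 below 0, median −0.69, mcsA −2.29, ctsR −2.27, 7 adjusted over the list alone), osmoprotectant uptake (up; 17 of 18 above 0, median 0.72, opuE 1.60, opuBA 1.10) and sulfur amino acids (down; median −0.76, yrhB −3.08, mccA −2.80). The others were the bkd operon, branched-chain synthesis, general stress and iron uptake (up) and the citric acid cycle, competence, carbon catabolite genes and envelope stress (down). Of these, some medians ran against the averaged direction: general stress −0.86 and branched-chain synthesis −0.12 in the mutant at 37 °C, competence 0.73 in the mutant in the cold, and carbon catabolite genes 0.15 in the wild type at 37 °C. None passed with an estimated correlation (smallest adjusted p = 0.282 with an estimated correlation), fry called the heat shock list (adjusted p = 0.0236), and 43 of 100 splits called as many. A model without blocks called 14 genes and the model with interactions 73.

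The replicated group allowed 2 planned contrasts. Between mutant and wild type in stationary cold cells limma called 0 genes (smallest adjusted p = 0.837; 229 genes at an unadjusted p under 0.05); yplP stood at −6.01 ± 0.52. In simulated data 0% of changes of a log2 fold of up to 4 were recovered by this contrast. All 28 motility genes lay above 0 (median 0.66; fliE 1.72, yviF 1.42) and 12 of 12 pyrimidine genes below 0 (median −0.98; pyrD −1.56, pyrK −1.44), among 11 lists that camera called, 4 up and 7 down, none of them with an estimated correlation (smallest adjusted p = 0.977 with an estimated correlation) or fry. For cold against 37 °C in the stationary mutant limma called 0 genes (smallest adjusted p = 0.105; 815 at an unadjusted p under 0.05), with the cold shock and desaturase genes at 0.46 to 6.85. camera called 14 lists there, 12 up and 2 down, none with an estimated correlation (smallest adjusted p = 0.873 with an estimated correlation) or fry. The added contrasts within exponential phase also gave 0 calls with limma: mutant against wild type in the cold (0.717; 288 unadjusted) and cold against 37 °C in the wild type (0.0831; 1052 unadjusted).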

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

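The tests on yplQ, tetB and a mislabelled library, and the list tests for cold by phase, were chosen after the result was seen.

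The cold effect differed between genotypes or phases, by a test of that difference, in the following genes. Between genotypes, mutant minus wild type, the log2 difference was −4.67 for yplQ. Between phases, stationary minus exponential, it was 5.86 for yjcZ, 3.91 for nasD, 3.63 for carA, 3.61 for yuaB, 3.60 for wapA, −5.45 for yrrT, −5.23 for tuaC, −4.92 for tuaG, −4.60 for tuaE and −1.80 for des. The fitted −5.84 for ykzW depends on the pseudocount and is no measure of size, since the gene was listed at 0 in the mutant exponential 37 °C library. Differences between phases are not separated from differences in time after transfer. Of 60 splits of the libraries that could be fitted, only the real one gave as many genes as the phase difference (104, highest other 34). That share is under 0.05, but other splits can be unbalanced over genotype and temperature and then hold less information. They are not equal draws of chance, so chance is not excluded. For the genotype difference 2 of 60 gave as many (1 gene, highest other split 2). That share is under 0.05, but another split called more, and a count of 1 gene is too small to exclude chance splits. With 9 libraries each split shares most libraries with the others.

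Gene lists differed by genotype with camera at the preset correlation, as medians of mutant minus wild type: −0.54 for the bkd operon, −0.45 for osmoprotectants, 0.25 for ribosomal proteins, −1.57 for purines, −1.67 for pyrimidines, −1.99 for arginine, −1.04 for histidine, −0.73 for nitrogen, −0.55 for motility, −0.65 for competence, −0.86 for the matrix, −0.34 for envelope stress and −0.52 for ATP synthase. None passed with an estimated correlation (smallest adjusted p = 0.587 with an estimated correlation, from limma's camera) and fry called 0. As many lists as these 13 were called in 9 of 60 splits (highest other 15), so chance splits cannot be excluded. The ribosomal list turned direction under quantile normalization and without the wild-type stationary 37 °C, wild-type stationary cold or mutant stationary 37 °C library.

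Lists differed by phase, as medians of stationary minus exponential: −0.67 for cold shock proteins, −1.18 for the desaturase system, 0.59 for osmoprotectants, 0.93 for general stress, 0.84 for ribosomal proteins, 0.57 for translation factors, 0.92 for glycolysis, 2.58 for purines, 1.39 for pyrimidines, 2.79 for arginine, 1.28 for histidine, 1.08 for tryptophan, 1.00 for nitrogen, 1.35 for motility, 1.93 for competence, 2.16 for the matrix, −0.76 for carbon catabolite genes, 0.66 for the prophage PBSX and 1.52 for ATP synthase. None passed with an estimated correlation (smallest adjusted p = 0.477 with an estimated correlation, from limma's camera) and fry called 0. Only the real split of 60 called as many lists, 1 of 60 (19, highest other 18). That share is under 0.05, but a margin of 1 list is too small to exclude chance splits.

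The pattern behind the genotype difference is that yplQ, directly downstream of yplP, was high in each mutant library at both temperatures, and so was tetB elsewhere on the chromosome. A mislabelled library is argued against by yplP itself, whose highest mutant value was 44.7% of the lowest wild-type value. Transcription that starts in or near the altered yplP gene and runs on into yplQ cannot be told apart from an effect of YplP on yplQ. The larger of the 2 cold folds of yplQ in the mutant was 0.07 in log2 units, but a like level at both temperatures is the pattern itself and so gives no support, and the kind of mutation is not stated. For tetB, a dependence on the level of yplP mRNA cannot be told apart from a difference between the strains: the cold effect in the mutant minus that in the wild type was 0.094 (95% interval −1.13 to 1.31), too wide to decide. Of the genes around tetB, 5 were tested, with yplP effects of −1.58 to 0.40 and 0 calls. Whether the mutation carries a resistance cassette, which would bear on this resistance gene, is not stated. An effect of YplP on either gene remains an open biological explanation.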

How the results depend on the processing

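The alternatives were planned before the data were examined except for the scalings and left-out libraries of the gene lists, the list tests for cold by phase, the contrasts within exponential phase, and the settings of ysbA and ysbB, which were chosen after the data were seen. With 1 library in 7 of 8 groups, low residual degrees of freedom limit each test, and depth limits the low genes, which scatter most in the replicate pair. No paired analysis was possible because no label pairs cultures by replicate number; the blocks of the main effects match libraries by condition only. The cause was not tested for any change below, save that leaving out a library also takes away a residual degree of freedom. The count of genes for the cold effect lay between 1024 and 1560 under the 10 other settings that keep every library and set no fold threshold, within 1.5 times of 1146, and at 528 to 1079 with a library left out. Of 121 named genes called for cold, 72 kept the call in every setting, 47 lost it without some library and 28 under some other setting, the 2-fold threshold included; for the yplP effect 1 of 12 kept it (tetB), for cold by genotype 0 of 1 and for cold by phase 0 of 40. Among 368 further named results that passed nowhere in the text, 89 of 6387 values changed sign and 59 passed. The planned count-model alternatives were not run, since the files hold no counts. In 14 cases leaving out a library of an 8-group contrast gave no value.

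Leaving out each library in turn gave 1 to 56 genes for the yplP effect, 0 to 14 for cold by genotype (14 without mutant stationary cold replicate 1), 0 to 425 for cold by phase and 0 to 3 for cold in the exponential wild type (3 without the mutant exponential 37 °C library). Single genes that did not pass and changed sign were, for the cold effect, ysbA (−0.59 to 2.40, negative without either wild-type exponential library); for the yplP effect, ysbB (−1.61 to 0.48) and gbsA (−1.30 to 0.17), both positive without either exponential cold library, and lytT (−0.36 to 0.036, positive without the wild-type stationary cold library); and for cold by genotype, ysbB (−4.90 to 0.48, positive without any exponential library). For the yplP effect, 58 genes were called under median-ratio scaling, 4 under quantile normalization, 49 at a minimum of 20 RPKM, 62 at a pseudocount of 5, 20 with rRNA and tRNA left out and 4 in the additive model, against 32. For growth phase the additive model called 14 and the model with interactions 73, against 0. For cold by genotype a pseudocount of 0.1 called 0, against 1. For cold by phase 245 were called with rRNA and tRNA left out, against 104. For the yplP effect in stationary cold the spread of the additive model gave 1, against 0. Quantile normalization gave 144 genes for the cold effect in stationary yplP cells and 290 for the cold effect in exponential WT cells, where a minimum of 20 RPKM gave 3, each against 0; it also turned cspD (−0.41) and srfAC (−0.031) in the cold effect.

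Of the gene lists, an estimated inter-gene correlation called 0 in the cold effect, the yplP effect, the growth phase effect, cold by genotype, cold by phase and the yplP effect in stationary cold. fry called 0 for the yplP effect, cold by genotype, cold by phase and the yplP effect in stationary cold, and 1 for the growth phase effect. Quantile normalization gave 10 lists for the yplP effect, against 6, and 7 for the yplP effect in stationary cold, against 11. The wild-type excess in exponential cold stayed between 5.86 and 6.06 for ysbA and between 4.87 and 5.12 for ysbB in log2 units. Under median-ratio scaling the median shift of the log2 folds of single genes was over 0.1 in size only for cold in the exponential wild type, at −0.103.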

Other observations

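The phosphate starvation, cytochrome bd, nitrate and lactate genes and the tests on ysbA, ysbB and tRNA, other than that on short mRNAs, were chosen after the result was seen.

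Some genes that B. subtilis turns on when phosphate runs short rose in the cold. Of 20 such genes, not tested as a list (the pst and tua operons, phoA, phoB, phoD, phoP, phoR and glpQ), 9 rose with limma and 20 lay above 0, with a median of 2.71. The others did not pass, among them phoD (0.17 ± 1.17, limma adjusted p = 0.932), phoP (0.42 ± 0.40, 0.47) and phoR (0.06 ± 0.34, 0.913). In single libraries the median cold fold was 4.93 in exponential wild-type cells (20 of 20 above 0), against 0.72 in stationary ones. In the mutant 19 of 20 lay above 0 in exponential cells, and the stationary median was 0.65. pstS, the phosphate binding protein, went from 154.6 to 17606.8 normalized RPKM in exponential wild-type cells and from 255.7 to 2393.4 in stationary ones. The difference between phases was called in 4 of the 20, all negative, with a median of −3.50. The yplP effect had 0 calls among them (limma, median 0.10).

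Of 4 genes for the oxygen-thrifty cytochrome bd oxidase and its assembly, 3 rose in the cold with limma. These were cydB (1.61 ± 0.42), cydC (3.33 ± 0.46) and, most, the assembly gene cydD (5.38 ± 0.40). cydD went from 195.1 to 18718.1 in the exponential wild type and from 262.1 to 6620.1 in the exponential mutant. cydA did not pass (0.18 ± 0.33, limma adjusted p = 0.726) and its fold in the exponential mutant was −0.68. Of 6 nitrate respiration genes 2 rose, narG and narH, while narK (1.06 ± 0.65, limma adjusted p = 0.26) and fnr (0.22 ± 0.46, 0.763) did not pass, nor did narI and narJ. Neither group was tested as a list. The lactate permease gene lctP went from 27554.9 to 145006.1 in the exponential wild type and from 62284.3 to 60700.9 in the exponential mutant. In stationary cells it was higher in the cold in both genotypes, at 10459.3 and 45350.9 in the wild type and at 11812.3 against 33327.5 and 47314.2 in the mutant. The genotype difference in its cold effect was not called (−1.33 ± 0.52, limma adjusted p = 0.748).

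tRNA genes were lower in the mutant, with a median log2 fold of −1.09 against −0.05 for mRNA genes. The authors' 1 scaling factor per library moves every gene alike, which the gap of −1.04 between tRNA and mRNA argues against. Loss of short transcripts in general is argued against by the 92 mRNA genes of up to 150 nt, whose median was 0.10 (95% bootstrap interval −0.19 to 0.26), although such genes can lie in longer transcripts. Differences between libraries in the share of small RNA cannot be told apart from the mutation: the 2 libraries of the replicate pair differed by −0.99 when medians were taken over the differences of single genes. In log2 units of tRNA over mRNA, taken as medians within each library, the pair lay further apart than the −1.04 between genotypes. On that scale each mutant library lay below the wild-type library of its condition: 3.83 against 4.61 and 3.28 against 5.20 at 37 °C, and 6.02 against 6.47 and both 6.22 and 5.01 against 6.68 in the cold. An effect of yplP itself remains open and was not tested further.

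ysbA and ysbB were high in the wild-type exponential cold library alone. The level of yplP mRNA by itself is argued against as the whole cause, since the wild-type stationary cold library had 92.4% of that yplP level but fell short of the matching ysbB and ysbA levels 126-fold and 197-fold. Read-through from lytS and lytT upstream is argued against by their cold folds in that library, at most 0.052 in log2 units. Chance variation of a single library cannot be told apart, since no second library of that group exists, although 0 of 670 genes at 5000 to 20000 in the replicate pair differed as much (largest 3.34). A joint need for active YplP and a state of exponential cells, or a time after transfer, may be a hypothesis to test, and these data hold 1 library of that kind.

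Splits of the 9 libraries into groups of the same sizes bear on each count; 100 of 126 were drawn for the main effects. For genes, only the real split of 100 called as many for the cold effect (1146 against a highest other of 807). The same held for the yplP effect (1 of 100, with 32 against 21). Labels were moved freely across blocks, and a split with all libraries of a block on 1 side compares fewer libraries. Such splits are not equal draws of chance, so these shares do not exclude chance. Of the 32 yplP calls, 20 were tRNA genes, and all 86 tRNA genes lay below 0. For growth phase the real count is 0, so 100 of 100 splits had as many by construction (highest other 170) and chance was not tested. Both splits that called 170 matched phase in 7 of 9 libraries, the 5 cold ones included, temperature in 5 of 9, and genotype in 6 of 9 for 1 split and 7 of 9 for the other. Each split kept both 37 °C libraries of a genotype on 1 side. The blocks of genotype and temperature then left only a comparison of stationary with exponential libraries in the cold. The 170 calls thus belong to a phase difference within the cold, or one in time after transfer, seen in splits picked by their count. For lists, chance splits cannot be excluded either. As many were called in 26 of 100 for the cold effect (13, highest other 16). The shares were 73 of 100 for the yplP effect (6, highest other 16) and 43 of 100 for growth phase (11, highest other 20).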
